A study of Citrus unshiu with 2 samples.

How the data were processed

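DNA methylation was measured by whole-genome bisulfite sequencing of shoots of Citrus unshiu, the satsuma mandarin, in 2 libraries. Bisulfite converts unmethylated cytosines so that they are read as thymine, and the cytosines that remain are counted as methylated. Levels are given for 3 sequence contexts, CG, CHG and CHH, where H is any base other than G. In plants the CG pattern is copied at replication by MET1, CHG methylation is kept by chromomethylases, and CHH methylation is set by RNA-directed DNA methylation and by CMT2. According to the labels' protocols, 20 trees were assigned to normal watering and 20 to water deficit in a rain-proof tunnel, and soil in the deficit group was allowed to dry to about 15% moisture in a treatment of 75 days. How many trees contributed to each library is not given in the sources used here. The protocols name the EZ DNA Methylation-Gold conversion kit, the Accel-NGS Methyl-Seq library kit and an Illumina NovaSeq sequencer. The submitters' processing notes name Bismark 0.20.1, SAMtools 1.4 and bedtools 2.26.0 without assigning a role. The genome build, the gene annotation, the read depth, the coverage required per cytosine, the conversion rate and the method that called regions are not given in the sources used here.

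The authors deposited 1 table per library with the methylation level, in percent, of each gene's promoter, 5' UTR, exons, introns, 3' UTR, gene body and downstream flank, for each context and for all cytosines together, per the file headers. The distance that defines a promoter or a downstream flank is not given in the sources used here. There were 29131 genes listed for normal water and 29138 for light drought, and the 29073 genes in both were used. The tables carry no read counts, so the depth is unknown and no interval or detection floor was computed. A level of 0 also stands where a gene has no such region or may have had no covered cytosine. The number of genes at 0 in both libraries was 3743 for CG in promoters and 22825 for CG in 5' UTRs. Means over all listed genes and means over genes above 0 in both libraries are therefore told apart.

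The authors also deposited 1 table of differentially methylated regions per context, which compares the 2 libraries. Each row gives the region, the number of cytosines, the difference in level in percentage points (a signed score), a p-value and a corrected p-value, per the file headers. The tables also hold 6 columns of levels per group, in percent, which were left out because their names match the labels of neither library. The planned check of the differences against those levels was therefore not made. Every region had at least 10 cytosines of its context. The highest p-value was 0.0482 for CG, 0.0488 for CHG and 0.0498 for CHH, so the lists go by the uncorrected p-value. In 1 CG region the corrected p-value lies below the uncorrected one. The corrected p-values also do not follow the order of the uncorrected ones. In CHH, a region with an uncorrected p of 1.34e-08 has a larger corrected p than one with 3.07e-06, whose corrected p is 0.125. How the corrected p-values were obtained is not given in the sources used here. The direction of the differences was taken as light drought minus normal water from the order in the name of the tables, and this was checked against the labelled gene tables, as reported with the regions. Starts are printed counted from 1. In the tables they were read as counted from 0. The reason is that the deposited overlap with a gene feature equalled end minus start in 98.9% of the CG, 97.5% of the CHG and 97.8% of the CHH regions that touch 1 feature, and was longer in none. Also, 26 CG regions ended where a neighbour started, while 0 overlapped a neighbour. The gene features of a region are those the authors assigned, and a region that touches several features was counted in each.

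With 1 library per group there is no spread between replicates, so no test between the conditions was made, and the values describe these 2 libraries. Differences are light drought minus normal water, in percentage points. SDs and SEs are over genes or regions, which are not replicates. Genes were counted as differing by a fixed size of 20 points in CG and CHG and 10 points in CHH. Regions of different contexts were paired when they shared at least 1 bp. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The size rule, the overlap and the merging of regions were tested on simulated data. On the normal water levels of 29073 promoters with added noise, the size rule recovered 200 of 200 planted genes in each context with 0 others. The overlap step recovered 200 of 200 planted overlaps among 5000 regions, and the merging step joined 200 of 200 planted neighbours among 5200 regions. The planted differences were set above the size rule. The added noise was far smaller than the real spread of promoter differences over genes (SD 10.7 points in CG, 9.39 in CHG and 5.39 in CHH). Full recovery was thus fixed by these settings. It checks the calculation and says nothing about false calls in the data.

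The comparisons, sizes, alternatives and naming rule were set before the data were examined, apart from those named here or in the closing part as later. The alternatives were the median, filters on low levels, other sizes, subtraction of the median difference, stricter or longer regions, merged regions and a larger required overlap. Lists of genes for flowering, hormones, drought and the methylation machinery had also been set, but could not be used. The tables pair gene identifiers with no names, and 0 of the identifiers matched the available reference table of the Citrus unshiu CUMW_v1.0 assembly, which itself gives locus tags only. Gene identifiers are printed as deposited. The naming rule took the genes with the largest gene-body differences that also hold a region of the same context and sign, and the 3 regions with the largest difference in each direction and context. Because the identifiers have no names, it was reduced to 2 genes that were higher and 2 that were lower, from CG and CHH. A level above 0 in both libraries stood in for a coverage minimum, a choice made after the data were seen. Weighting genes by their cytosines or reads and raising a coverage minimum could not be done without counts.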

Results

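The series compared the shoot methylome of Citrus unshiu trees under light drought with that of normally watered trees, in a study of flowering branches formed under mild water deficit. It holds 1 bisulfite library per condition. Both libraries gave levels for 29073 genes in common, while 58 genes were listed only for normal water and 65 only for light drought. Across genes, the promoter levels of the libraries were correlated with Pearson's r of 0.945 in CG, 0.948 in CHG and 0.924 in CHH, over genes that are not independent replicates. No replicate supports any difference below, and the read depth behind each level is unknown.

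The first comparison asked how methylation in and around genes differed between the libraries. CHH methylation of promoters was higher in the light drought library, with a mean over genes of 12.7% against 10.3% under normal water, a difference of 2.40 points (SD 5.39 over 29073 genes). Relative to normal water this was 23.2% more. CHH in downstream flanks was higher by 1.53 points, at 8.62% against 7.09%, or 21.5% more. The median CHH differences over all listed genes were smaller, at 0.95 points in promoters and 0.07 points in downstream flanks. Gene bodies carried little CHH methylation in either library, with 3.51% under light drought and 3.08% under normal water, or 13.8% more. CG and CHG methylation of promoters was higher by 1.41 and 1.37 points, from levels of 30.5% and 23.9% under normal water, which amounts to 4.63% and 5.72% more. The medians were 0.25 and 0.16 points. In gene bodies the CG level was 37.3% against 36.5% and the CHG level 12.7% against 12.5%. Over all cytosines, the promoter level was 16.8% under light drought and 14.6% under normal water.

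Most promoters shared the direction in CHH. Among the 25386 promoters above 0 in both libraries, 76.2% were higher under light drought and 23.5% were lower, with means of 14.4% and 11.7%. The corresponding share of higher genes was 74.7% for downstream flanks in CHH, 60.7% for promoters in CG and 62.8% for promoters in CHG. Exons and introns showed smaller CHH differences of 0.436 and 0.653 points among genes above 0 in both, and of 0.348 and 0.337 points over all listed genes. The latter amount to 13.05% and 15.7% more than under normal water. In CG, 3' UTRs stood at 54.8% against 50.8% over the 10545 genes above 0 in both, a difference of 4.02 points (SD 13.2), next to 2.48 points in downstream flanks. Over all listed genes, of which 16946 were at 0 for the 3' UTR in both libraries, the 3' UTR difference was 1.55 points with a median of 0, next to 1.71 points in downstream flanks. The 5' UTRs differed in CG by 0.549 points (SD 7.89) over 3966 genes above 0 in both and by 0.0713 points over all listed genes.

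**Figure D1:**
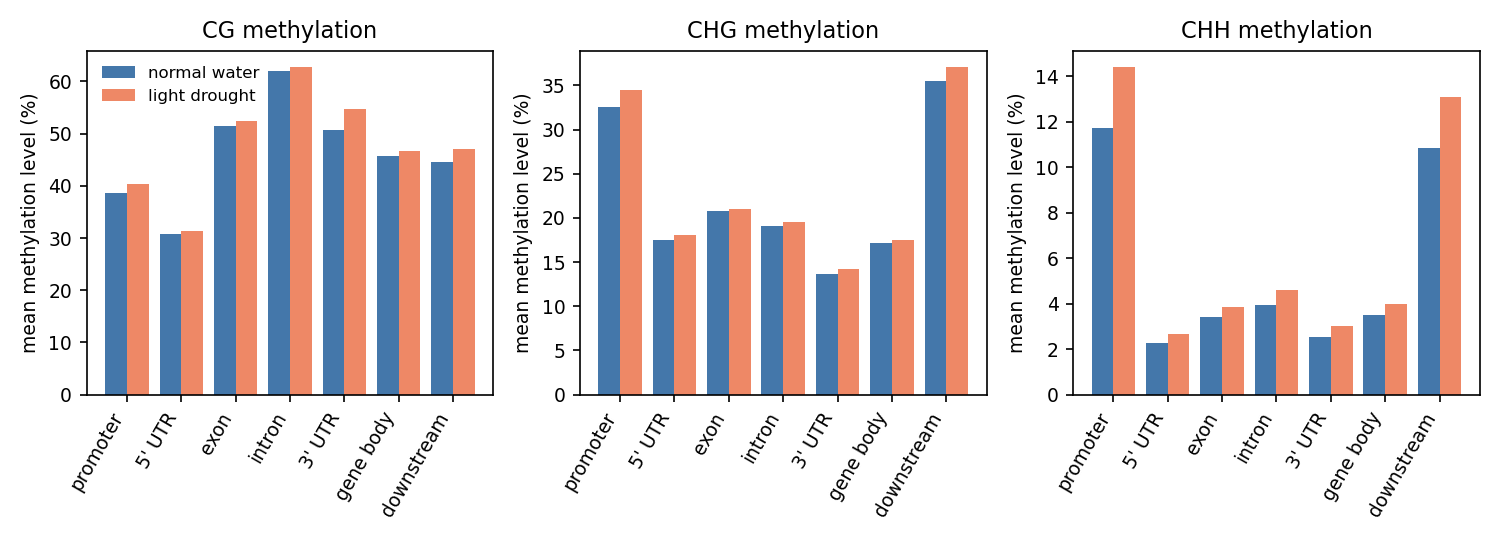
Mean methylation level in percent (vertical axes, each from 0) of 7 gene regions (horizontal axes) in the normal water library (blue) and the light drought library (orange), over genes above 0 in both, with 1 library per bar and so no error bars. CHH in promoters stands at 14.4% against 11.7%, and CG in 3' UTRs at 54.8% against 50.8%.

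The CHH promoter difference was positive on all chromosomes. Over the 9 numbered chromosomes and the unplaced sequence, the mean promoter difference in CHH lay between 2.18 points on chromosome 9 and 2.68 points on chromosome 4. The promoter differences ranged from 0.992 to 1.94 points in CG and from 0.72 to 1.79 points in CHG, with the lowest value of both in the unplaced sequence. Gene-body CHG differences ranged from 0.0223 to 0.353 points.

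The difference in percentage points varied with the level of methylation. Genes were grouped by the level averaged over both libraries, which leaves out those at 0 in both and keeps those at 0 in 1 library. Promoters with an average CHH level above 0 and up to 1% differed by 0.0924 points (6010 genes), at 0.472% against 0.379%. Those between 10 and 20% differed by 3.48 points (6235 genes), at 16.5% against 13.0%. Those between 30 and 40% differed by 6.40 points (1591 genes, 85.4% of them higher), at 37.4% against 31.0%. A low average level limits how many points a gene can differ by, so small values at low levels are partly set by the grouping. In proportion to normal water, the difference was not smaller in the lowest group than between 30 and 40%. Between 60 and 80% the difference was 3.90 points (109 genes). In CG, promoters between 30 and 40% differed by 3.36 points and those above 80% by 0.402 points. CHG-rich gene bodies, with levels above 80%, differed by -0.227 points (2221 genes), and 44.9% of them were higher under light drought.

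**Figure D2:**
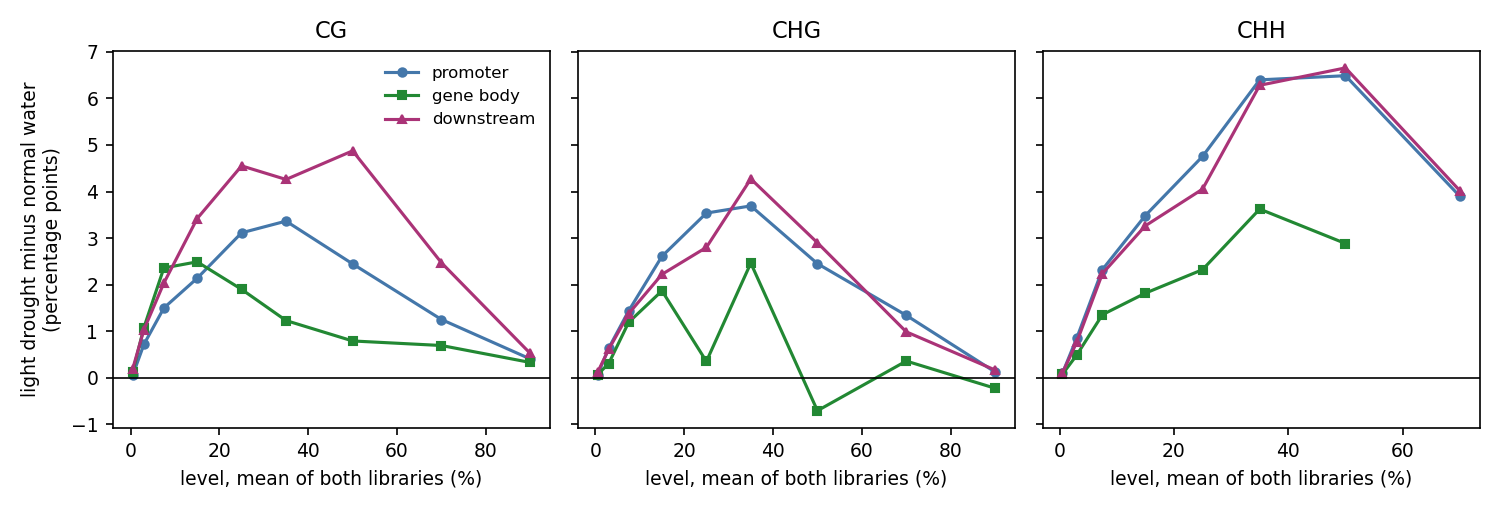
Mean difference between the light drought and the normal water library in percentage points (vertical axis) against the level averaged over both libraries in percent (horizontal axes, bins drawn at their midpoints), for promoters (circles), gene bodies (squares) and downstream flanks (triangles). Bins with fewer than 20 genes are not drawn. In CHH promoters the difference goes from 0.0924 points in the lowest bin to 6.49 points between 40 and 60% and 3.90 points between 60 and 80%.

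By the fixed size of 10 points, CHH in promoters was higher under light drought in 1848 genes and lower in 212, so that 89.7% of these genes were higher. In gene bodies 220 genes were higher and 107 lower in CHH. Without genes listed at 0 in either library these became 171 and 47, which moved the share of higher genes from 67.3% to 78.4%. By 20 points, CG in promoters was higher in 764 genes and lower in 479, and CG in gene bodies higher in 345 and lower in 225. CG in 3' UTRs was higher in 1247 genes and lower in 397. CHG in promoters was higher in 605 genes and lower in 349, and in gene bodies higher in 179 and lower in 162. At 30 points the order of the CHG gene bodies turned, with 104 higher and 114 lower. Without genes listed at 0 in either library, the gene-body counts at 20 points became 238 higher and 102 lower in CG, and 94 and 65 in CHG. These counts depend on the size chosen, and without replicates they include differences that sampling of reads alone can make.

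The genes with the largest gene-body differences among those that also hold a region of the same context and sign are named by identifier. Cs8g01060 had a CG gene-body level of 76.8% under light drought and 6.35% under normal water. Its promoter stood at 64.1% against 28.0%, and the authors' deposited table has a CG region in the promoter on chromosome 8 at 62263 to 62437. This was the only CG region listed for the gene, so none was listed in its gene body. Its CHG and CHH gene-body levels were at most 1.30% in either library. Cs1g02330 had the opposite direction in CG, with 57.1% under light drought against 95.1%. There the CHG level was also lower, at 44.3% against 78.4%, and the authors' deposited table has a CG region over exon and 3' UTR at 1649834 to 1650023 of chromosome 1. In CHH, Cs1g15230 stood at 67.7% under light drought, 38.6 points above normal water, while its CHG level was 88.9% against 89.1%. The authors' deposited table has an exonic CHH region there on chromosome 1 at 18454713 to 18454760. Cs8g04270 stood at 2.81% against 24.1% in CHH gene-body level, while its promoter was at 48.6% against 27.1%. The authors' deposited table has a lower CHH region there over exon and promoter, on chromosome 8 at 2233746 to 2233804. Its direction is opposite to that of the promoter level, but the promoter in question may be that of a neighbouring gene. For this region and that of Cs1g02330, which feature belongs to which gene was not resolved.

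The second comparison concerned the differentially methylated regions. CHH regions made up most of them, and most CHH regions had the higher level under light drought. The authors' deposited tables list 2782 regions in CG, 3250 in CHG and 82479 in CHH. How many regions could be tested in each context is not known here, so these counts do not rank the contexts. In CHH, 66142 regions were higher under light drought and 16337 were lower, so that 80.2% were higher. In CG the counts were 1947 higher and 835 lower, or 70.0% higher, and in CHG 2001 and 1249, or 61.6% higher. The mean difference over regions was 12.9 points in CHH, 10.7 points in CG and 4.88 points in CHG. Among CHH regions, the median difference was 19.3 points for those that were higher and -16.4 points for those that were lower. The regions were short, with median lengths of 89 bp in CG, 107 bp in CHG and 47 bp in CHH and a median of 10 cytosines in each context, and they covered 265010, 373539 and 4642143 bp.

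Few regions had a small corrected p-value. Since the corrected p-values do not follow the order of the uncorrected ones, these counts cannot be read as an ordinary correction of the listed p-values. In the authors' deposited tables the corrected p-value was under 0.05 in 23 CG regions, 17 CHG regions and 223 CHH regions, which is 0.827%, 0.523% and 0.270% of each list. Of these, 20 in CG, 11 in CHG and 204 in CHH were higher under light drought. The share of higher regions was larger at smaller uncorrected p-values in CHH and CG. In CHH it was 75.4% for p-values from 0.01 to 0.05 and 89.8% for those below 0.0001, and in CG it was 63.8% and 76.8%. In CHG it was 59.8% for p-values from 0.01 to 0.05, 58.6% from 0.001 to 0.01 and 67.5% below 0.0001. The authors' p-values compare cytosines of 2 libraries and do not measure the spread between trees.

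Directions of regions and of gene levels were compared where both were given. In promoters with regions, the gene-level difference had the sign of the region in 85.0% of 360 genes in CG, 85.0% of 468 genes in CHG and 83.7% of 8449 genes in CHH. For gene bodies the shares were 84.9%, 84.1% and 80.3%. The direction given here for regions rests on the order in the name of the tables and on these shares. Shares for independent directions were not computed. They would be larger in CHH, where 82.4% of promoter regions and 76.2% of promoters above 0 in both libraries were higher, than in CG, with 63.7% and 60.7%. The CHH agreement is therefore the weaker check.

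The location of the regions differed by context. In CHH, 65.4% of regions lay outside any annotated gene feature, 17.3% in promoters, 11.5% in downstream flanks and 2.64% in exons. In CG, 35.6% lay outside gene features, 32.0% in exons, 12.8% in promoters, 12.4% in downstream flanks and 7.73% in 3' UTRs. In CHG, 1301 of 3250 regions lay outside gene features, 28.2% in exons, 15.7% in introns and 13.9% in promoters. No background of all testable regions was used here, so these shares are not enrichments. Chromosomes did not differ widely in direction, with 78.9 to 81.6% of CHH regions, 66.7 to 75.6% of CG regions and 57.2 to 68.2% of CHG regions higher under light drought.

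By feature, 82.4% of the 14278 CHH regions in promoters were higher under light drought, with a mean difference of 14.7 points (SD 16.8 over regions), and 73.7% of the 2178 CHH regions in exons. Of the 215 CG regions in 3' UTRs, 185 were higher and 30 lower, and their mean difference was 24.3 points (SD 23.0 over regions). Of the 68 CG regions in 5' UTRs, 37 were higher and 31 lower. CG regions in promoters were higher in 226 of 355 cases.

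**Figure D3:**
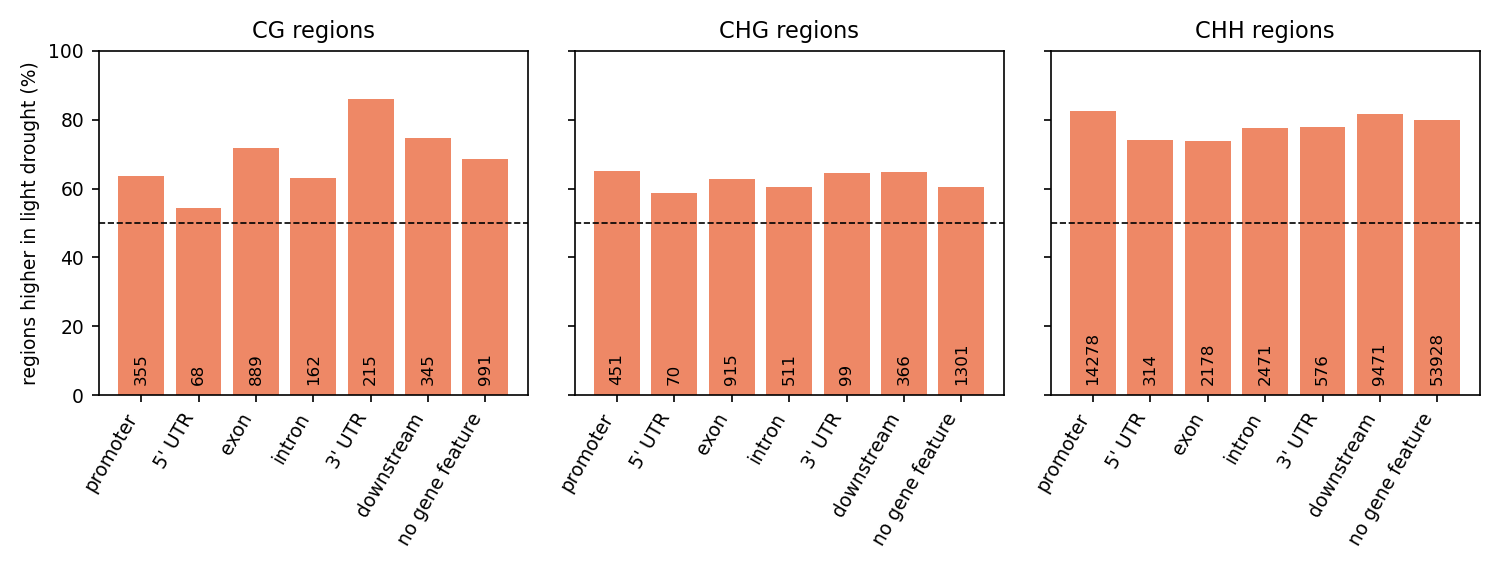
Share of the authors' regions with the higher level under light drought, in percent (vertical axis, from 0), by annotated gene feature (horizontal axes) and context. The number in each bar is the count of regions and the dashed line marks 50%. The share is 86.0% for CG regions in 3' UTRs and 82.4% for CHH regions in promoters.

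Regions of different contexts coincided in part. CG and CHG regions overlapped in 275 pairs, which involved 9.74% of the CG regions, and 273 of the pairs had the same direction, 195 with both higher under light drought and 78 with both lower. That is 99.3%, where independent directions would give 59.0%. CG and CHH regions overlapped in 268 pairs with 82.1% of the same direction, against 68.6% for independent directions. CHG and CHH regions overlapped in 521 pairs with 83.5% of the same direction, against 65.0%.

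The regions with the largest differences reached over 80 points. In the authors' deposited table for CHH, a region of 22 cytosines downstream of a gene, at 26851706 to 26851797 of the unplaced sequence, was higher under light drought by 86.9 points with a corrected p of 1. Its uncorrected p there was 1.34e-08. In the same authors' deposited table, a region of 26 cytosines outside gene features, on chromosome 5 at 4625728 to 4625869, was higher by 83.8 points with a corrected p of 0.00016. The CHH region with the largest difference in the other direction was in a promoter on chromosome 2 at 3138114 to 3138234, with -63.8 points and a corrected p of 0.397 in the authors' deposited table. In the authors' deposited table for CG, a region of 10 cytosines in a downstream flank on chromosome 4 at 1606618 to 1606639 was higher by 83.7 points, and a promoter region on chromosome 4 at 18694966 to 18695150 differed by -80.8 points, both with a corrected p of 1. In the authors' deposited table for CHG, an exonic region on chromosome 7 at 29092730 to 29092822 was higher by 78.3 points, with a corrected p of 1. A CHG region over exon and intron at 32662326 to 32662449 of the unplaced sequence differed by -75.3 points, with a corrected p of 0.486 in the authors' deposited table. The genome build of these coordinates is not given in the sources used here.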

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

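The settings with a corrected p under 0.05 and with genes above 0 in both libraries for the counts were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and no library could be left out for the same reason. A value counted as moved when it changed by more than 1.5 times, since neither a replicate spread nor a depth was at hand. Of 210 recalculated values, 102 did not move, 107 moved and 1 changed sign. The sign change was the CHG difference in 5' UTRs, 0.0238 points over all genes and -0.185 points over genes with a level of at least 5%; the cause was not tested. Many genes are listed at 0, and the medians over all genes were 0.25 (CG promoter), 0.11 (CG gene body), 0 (CG downstream), 0.16 (CHG promoter), 0 (CHG gene body and downstream), 0.95 (CHH promoter), 0.09 (CHH gene body) and 0.07 points (CHH downstream). With levels of at least 5% the means became 2.87 (CG downstream), 2.16 (CHG promoter), 0.477 (CHG gene body), 1.89 (CHG downstream), 3.97 (CHH promoter), 1.86 (CHH gene body), 1.90 (CHH exon, from 0.348), 2.35 (CHH intron, from 0.337) and 3.67 points (CHH downstream), and those of other UTRs and introns moved too. Above 0 in both libraries, the CHG downstream mean was 1.52 points.

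With a smaller fixed size (10 points, or 5 in CHH), the promoter counts were 2854 higher and 1384 lower in CG, 2364 and 1016 in CHG, and 5900 and 619 in CHH. Gene-body counts were then 1267 and 604 in CG, 502 and 411 in CHG, and 800 and 260 in CHH. With 30 points, or 15 in CHH, promoter counts were 306 and 231 in CG, 253 and 190 in CHG, and 625 and 106 in CHH. Gene-body counts were 159 and 140 in CG, 104 and 114 in CHG, and 100 and 61 in CHH, so that in CHG gene bodies more genes were lower than higher at this size, whose cause was not tested. Restricting to genes above 0 in both left 291 promoters and 102 gene bodies lower in CG, 180 promoters lower in CHG, 94 gene bodies higher and 65 lower in CHG, and 47 gene bodies lower in CHH. Subtracting the median difference moved no count by more than 1.5 times.

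At a corrected p of at most 0.001, 7 CG regions were higher and 0 lower, 1 CHG region was higher and 0 lower (100% higher), and 23 CHH regions were higher and 2 lower. At a corrected p under 0.05 the counts were 20 and 3 in CG, 11 and 6 in CHG, and 204 and 19 in CHH. With differences of at least 30 points, or 20 in CHH, they were 510 and 92 in CG, 268 and 139 in CHG, and 30806 and 4917 in CHH. With at least 100 bp they were 774 and 333 in CG, 1138 and 671 in CHG, and 7041 and 1036 in CHH. Among the larger differences, the shares that moved were CG outside gene features (22.3%), CG in 3' UTRs (16.3%, from 7.73%), CG in 5' UTRs (0.997%, from 2.44%), CHG in introns (29.2%, from 15.7%) and CHH in exons (1.52%, from 2.64%). More regions were higher than lower in each context under each of these settings. Merging neighbours, the larger required overlap and the limit to genes with regions of 1 sign moved no value by more than 1.5 times. Stricter settings give fewer genes and regions by construction, and the cause of the shifts in location was not tested. Weighting by cytosines or reads and a coverage minimum of 10 were not run for want of counts, and the gene-list alternatives were not run for want of names. Depth limits all levels to an unknown degree.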

Other observations

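The gene classes, the 3' UTR comparison and the windows used here were chosen after the region and gene totals had been seen. The tests on CHH levels near genes were chosen only after the result was seen, as was the bootstrap interval for the crowded windows, which was added once their ratio was known. Genes were grouped by their exons, averaged over both libraries. The remaining 3759 genes form a class of other genes. The 10961 genes with a CG level of at least 20% and a CHG level under 5% carry methylation of the gene-body type. The 4457 genes with a CHG level of at least 20% resemble silenced sequence, since CHG methylation in plants marks transposons and repeats. In 9896 genes, the low class, both levels were under 5%. Only 2564 of them were above 0 in both libraries for CG in exons, and a level of 0 may mean no covered cytosine. Class means are over the genes above 0 in both libraries for the region in question. Promoter CHH was higher under light drought in all classes, by 3.03 points (SE 0.0506 over 9526 genes) where exons carried CG only, by 2.48 points (SE 0.0743 over 4085 genes) where they carried CHG, by 2.44 points (SE 0.0545 over 8477 genes) in the low class, and by 2.67 points (SE 0.0828 over 3298 genes) in other genes. Inside genes the classes differed in CHH level and in the difference in points. CHH exon levels were 17.1% against 15.4% in 4257 CHG-methylated genes, 0.579% against 0.477% in 9868 genes with CG only and 0.418% against 0.334% in 4848 of the 9896 genes of the low class. In proportion to normal water, the difference was smaller in the CHG-methylated class than in genes with CG only or in the low class. CHG exon levels in the CHG-methylated class were 72.8% and 72.5%.

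Gene-level differences in the contexts were positively but weakly related across the 29073 genes, which are not independent replicates. For promoters, Pearson's r was 0.371 between CG and CHG, 0.356 between CHG and CHH and 0.277 between CG and CHH. For gene bodies it was 0.425, 0.324 and 0.187 for the same pairs. Genes listed at 0 in 1 library only were included, in gene bodies 2484 in CG, 4237 in CHG and 1708 in CHH. A gene without covered cytosines in 1 library would tend to differ with the same sign in all contexts. How much such genes add to r was not tested.

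CHH levels near genes were higher in the light drought library, and less complete bisulfite conversion would raise unmethylated cytosines everywhere. In 8917 genes with a CG gene-body level under 5%, genes listed at 0 included, the CHH gene-body level was higher by 0.0984 points (SE 0.0263 over genes) and the promoter level by 2.11 points. In the 5127 of them above 0 in both libraries for both regions the differences were 0.162 points (SE 0.0221) and 2.37 points, which argues against conversion as the whole cause, and this restriction was added after the first values were seen. Genes listed at 0 in 1 library do not account for it either, since the promoter difference was 2.70 points without them. A response to light drought cannot be told apart from a difference between trees, shoots or libraries, because there is 1 library per group.

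CG levels of 3' UTRs were higher in the light drought library. In 7694 genes with CG only in their exons the 3' UTR level was 56.4% against 51.9%, a difference of 4.49 points (SE 0.155 over genes) with genes at 0 in either library left out, while exons of the same genes differed by 0.273 points (SE 0.0710). A gain at all CG sites of intermediate level could produce this. Exons weighted to the CG levels of the 3' UTRs differed by 0.843 points (SE 0.0604). These exons came from a wider set of 15853 genes. The set had a CHG exon level under 5% and a CG exon level above 0 in both libraries. Exons of like mean level thus differed by less than 3' UTRs did. The levels are averages per gene region and those of single sites are unknown, so a gain at sites of intermediate level was not excluded. The difference was not particular to 3' UTRs or to this class, since downstream flanks of the class were higher by 3.55 points (SE 0.145) and promoters by 1.97 points (SE 0.0893), and in the class of other genes 3' UTRs stood at 53.3% against 49.5% and exons were higher by 2.11 points (SE 0.117). A response to light drought was not tested, with 1 library per group.

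A small part of the CG regions called by the authors was crowded, with 131 of 2782 in 7 windows of 50 kb with at least 10 regions each and the other 2651 spread over 1926 windows, and 50 of the crowded regions lay between 69054224 and 69060754 of the unplaced sequence, 42 higher and 8 lower under light drought. Other windows ran the other way, such as 10 lower and 0 higher between 23019971 and 23022357 of chromosome 7, or had no dense CG sites, with 11.3 per 100 bp and a median of 18.8 points between 17607215 and 17619467 of chromosome 7. Sequence present in many copies, where deep coverage lets small differences pass, is a possible explanation. The median absolute difference was 9.74 points in these windows and 20.0 points elsewhere, a ratio of 0.488 with a 95% bootstrap interval over regions of 0.434 to 0.551. The ratio itself lay under the 0.5 set in advance, but the interval, which was added later, straddles it. Resampling regions also leaves out the spread between the 7 windows, so the test did not decide. Taken over all 7 windows, regions were also denser in CG sites, with a median of 20.0 per 100 bp against 12.5, and without read counts the depth there cannot be told apart from that density.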
